A study of Mus musculus with 3 samples.

How the data were processed

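Single-cell RNA sequencing was run on CD11b+ cells of mouse fetal brain at embryonic day 18.5. Per the labels' protocols, brains were minced, cells were taken from a Percoll gradient, and cells carrying CD11b, an integrin chain of myeloid cells, were enriched with magnetic beads. Droplet libraries that read the 3' end of each transcript were made with 10x Genomics beads and sequenced on a NovaSeq6000. There were 3 libraries, 1 per group: Ncr1-cre with saline, Ncr1-cre with poly(I:C), and Gzmb-cko with poly(I:C), whose genotype is Ncr1-cre;gzmbf/f. Poly(I:C) is a synthetic double-stranded RNA that mimics a viral infection. Ncr1-cre drives recombination in natural killer cells and related innate lymphoid cells, and Gzmb encodes granzyme B, a protease of cytotoxic granules. The labels describe groups of pregnant mice; the dose and day of the injection, the number of fetuses pooled and whether the genotype is that of the dam or of the fetus are not given in the sources used here.

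The deposited matrices hold raw UMI counts per gene and cell barcode, without normalisation. Per the file headers they were written by Cell Ranger 5.0.0, while the submitters' processing notes name Cell Ranger 3.0.1, STAR and the mouse build mm10. Barcodes were already reduced to called cells, and the rule for calling them is not stated. The lowest UMI total of a barcode was 3133 in the saline library and 500 in both poly(I:C) libraries, so the libraries entered with different lower limits. Cell Ranger counts only reads that map to 1 gene, so genes with near-identical copies, and genes that overlap on the same strand, lose reads in proportion to their similarity. Each table held 27998 genes. For positions and transcript lengths, 27645 gene IDs (98.7%) were matched to the mouse annotation of build GRCm38 (mm10). Of 606 genes in the fixed markers and lists, 602 were matched by symbol, and Clec7a, Igkc, Trbc2 and Trdc were not analysed here.

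Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with Scrublet as run by scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes, and removed. The 3 libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes detected in at least 10 cells, 30 principal components, 20 neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2) were used. A cluster was named when at least 3 fixed markers of a class were detected in at least 20% of its cells and exceeded the mean of all clusters by a log2 fold of 1 (pseudocount 5 counts-per-million, CPM). It was left unnamed when a second class with at least 3 such markers reached 0.6 of the best class's mean log2 fold. It was also left unnamed when another class led its top 10 genes, or when its cells had few UMIs and no leading marker. The markers were fixed before the data were examined, and the details of the naming rule were not. Class names mean that cells resembled the class by these markers.

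UMIs were summed over the cells of a class in each library and given as CPM of the class total. Cells are not replicates, and with 1 library per group no test of treatment or genotype exists, so no p-value is given. Intervals are exact at 95%: Poisson for a level, conditional binomial for a ratio and Clopper-Pearson for a share. For levels, ratios and shares of cells these intervals cover counting error only, and the differences between libraries have no replicate check. Intervals of a share of genes, or of a median over genes, treat the genes as independent, which they are not. Those intervals measure neither counting error nor variation between libraries. Where a gene had 0 UMIs, 3 counts were taken as the limit. The cell filter, clustering parameters, markers, gene lists, comparisons and the rule for naming genes were fixed before the data were examined. In the microglia-like class that rule took genes with at least 20 CPM in the higher library, at least 100 UMIs over both libraries, a ratio of at least 1.5 and the same direction under TMM scaling and the mean of per-cell CPM. Of these, the 12 largest ratios per direction were named in each comparison with the Ncr1-cre poly(I:C) library, and 6 per direction in the remaining comparison. Markers of other classes, sex-linked Xist and Y genes, mitochondrial, ribosomal protein, hemoglobin and predicted genes were left out of this ranking. In other classes with at least 200 cells in every library, 5 genes per direction were taken. Members of each list were named by size, at most 4 per list.

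For each gene list, members with a mean of at least 10 CPM over the 3 libraries were used. The median of their log2 ratios (pseudocount 1 CPM) was given with its percentile among 10000 random lists matched on expression in 20 bins, as a description only. A second percentile, from lists matched on transcript length as well in 5 bins, was added after the data were seen. So was the difference between each member and the median of the 20 genes outside the list nearest in length, the length being that of the longest annotated transcript. The interval of the median difference is an order-statistic interval over the members of the list. Cycling cells were counted after each microglia-like cell had been thinned to 3142 UMIs, the 10th percentile of the class, as those with UMIs of at least 3 different genes of the G2 and M phase list. Microglia-like cells were also clustered again at resolution 0.6.

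The steps for the saline comparison were tested on 1 simulated set built from these libraries. Of genes given a true ratio of 1.5, 34 of 67 passed the size rule (50.8%), as a threshold set at the true value allows. All 67 genes given a ratio of 2 and all 66 given a ratio of 3 passed, and 0 of 5504 unchanged genes passed. The interval held the true ratio for 94.7% of 4382 genes, and 7 of 200 unchanged lists (3.5%) fell outside the central 95% of random lists. These figures apply to the comparison of the Ncr1-cre libraries alone and contain no variation between animals. Another 20 simulated sets without any change gave the covariance and correlation of ratios that share a library.

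Alternatives covered looser and stricter cell filters, doublets kept, resolutions 0.5 and 2.0, centring per library, scaling by TMM (edgeR 4.0.16), by median of ratios (DESeq2 1.42.0) or by a total without mitochondrial, ribosomal and hemoglobin genes, the mean of per-cell CPM, thinned cells, and the class without cycling or hemoglobin-rich cells. Cycling cells were here those with UMIs of 2 or more genes of the S phase and the G2 and M phase lists, without thinning. After the data were seen, further alternatives were added. These were a floor of 3133 UMIs in every library, the length-matched lists, thinning to 3133 UMIs, and a class that includes the border-associated macrophage-like cluster led by Spp1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.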

Results

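The 3 libraries were each from the CD11b+ cells of fetal brains of 1 group of pregnant mice. They compare fetal brain myeloid cells with and without maternal poly(I:C), and with and without the Gzmb-cko genotype under poly(I:C). No Gzmb-cko library with saline was among them. A genotype difference present without poly(I:C) therefore cannot be told from a changed response to it. Whether granzyme B of Ncr1-expressing cells is needed for a response cannot be answered here. The libraries held 13820 barcodes and 89295907 UMIs for Ncr1-cre with saline (saline), 14887 and 85442198 for Ncr1-cre with poly(I:C), and 15306 and 105574073 for Gzmb-cko with poly(I:C) (Gzmb-cko). Median UMIs per barcode were 5321, 4765 and 5800.5. Values of the 3 libraries are given in this order throughout. After the filter and doublet removal 11690, 10440 and 12889 cells remained. Barcodes under 3133 UMIs, the lowest total of the saline library, made up 0, 31.9 and 19.0% of the barcodes.

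Gzmb (ENSMUSG00000015437, mm10 chromosome 14, 56258838 to 56262260), the gene carried as a floxed allele by the Gzmb-cko group, was detected in a handful of cells. It had 61 UMIs in 4 barcodes of the saline library, 127 in 6 barcodes of the Ncr1-cre poly(I:C) library and 2 in 1 barcode of the Gzmb-cko library. As CPM of all UMIs of the library these are 0.683 (95% interval 0.523 to 0.878), 1.49 (1.24 to 1.77) and 0.0189 (0.0023 to 0.0684). Nearly all of these UMIs (60, 126 and 2) lay in the B cell-like cluster, which also held most UMIs of Gzma and Ncr1. In microglia-like cells no Gzmb UMI was seen, which allows up to 0.0805, 0.0833 and 0.0496 CPM. The deleted part of the floxed allele is not given in the sources used here, so 3' tags may come from outside it. Gzma, which encodes another cytotoxic protease and is not the targeted gene, had 183, 990 and 36 UMIs in 11, 17 and 2 barcodes. Of the 990, 109 lay in 1 barcode of the erythroid-like class. Ncr1 (ENSMUSG00000062524, chromosome 7, 4337724 to 4345164), which encodes the receptor NKp46 and whose promoter drives the recombinase, had 8, 6 and 0 UMIs. Prf1, which encodes perforin, had 4, 3 and 4 UMIs. The lower Gzmb of the Gzmb-cko library thus came with fewer UMIs of Gzma and Ncr1, and these counts do not separate fewer lymphoid cells from less Gzmb per cell.

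Microglia-like cells, named by P2ry12, Tmem119 and Sall1 among others, were the largest class in every library, at 60.2% (59.3 to 61.1), 63.3% (62.4 to 64.2) and 68.1% (67.3 to 68.9) of kept cells. Border-associated macrophage-like cells, the macrophages of the meninges and choroid plexus, were 7.12% (6.66 to 7.60), 5.09% (4.67 to 5.53) and 9.79% (9.28 to 10.3). Monocyte-like cells were 7.87% (7.39 to 8.37), 6.45% (5.98 to 6.93) and 4.24% (3.90 to 4.61). Neutrophil-like cells were 3.13% (2.82 to 3.46), 4.34% (3.96 to 4.75) and 1.27% (1.08 to 1.47). Erythroid-like cells were 7.84, 3.13 and 1.52%, choroid plexus-like cells 3.57, 8.57 and 8.11%, and neuron-like cells 3.52, 6.27 and 3.99%. Rarer were B cell-like cells (0.616, 0.670 and 0.551%), megakaryocyte-like cells (0.317, 0.287 and 0.737%) and radial glia-like cells (0.462, 0.354 and 0.233%), while 5.33, 1.54 and 1.44% of cells stayed unnamed. These small shares moved with the settings: unnamed cells were 4.91, 4.58 and 4.10% with doublets kept, and megakaryocyte-like cells 0.263, 0.473 and 0.890% under the looser filter. Radial glia-like cells were 0.445, 0.279 and 0.067% with doublets kept. B cell-like cells were 0.351, 0.307 and 0.388% at resolution 2.0, which reverses the order of the libraries. The CD11b beads and the different lower limits of UMIs both shape these shares. With at least 3133 UMIs required in every library, monocyte-like cells were 7.87, 8.14 and 4.78%, choroid plexus-like cells 3.57, 5.38 and 3.83%, and neuron-like cells 3.52, 5.53 and 2.80%. Under the stricter cell filter monocyte-like cells were 8.31, 10.0 and 5.71%, highest in the Ncr1-cre poly(I:C) library. Neuron-like cells were 1.74, 1.73 and 1.74% under that filter and 2.05, 3.05 and 3.24% at resolution 0.5, so their difference depended on filter and clustering. Choroid plexus-like cells were 5.53, 8.86 and 8.36% at resolution 2.0, and erythroid-like cells 13.6, 8.14 and 2.68% under the looser filter. With that floor microglia-like cells were 60.2, 64.7 and 71.6%, and border-associated macrophage-like cells 7.12, 6.05 and 10.9%. The border-associated class was itself mixed differently: its cluster led by Spp1 and Gpnmb, which also carried microglial markers, held 71.0, 48.4 and 44.1% of the class.

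**Figure D1:**
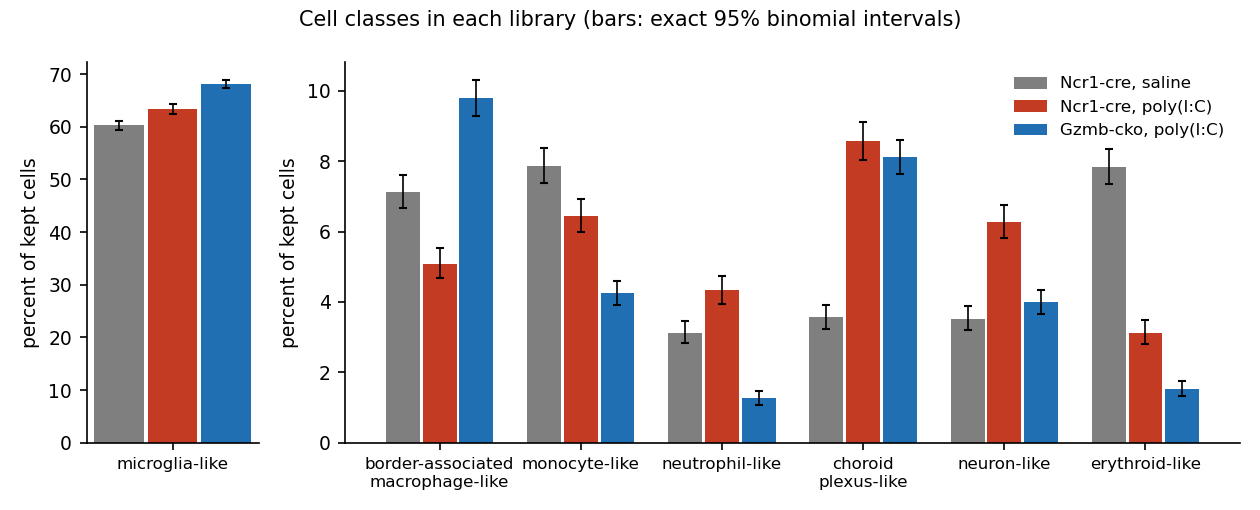
Percent of kept cells (vertical axis) in 7 cell classes for the saline, Ncr1-cre poly(I:C) and Gzmb-cko poly(I:C) libraries, with exact 95% binomial bars that cover counting error only. Microglia-like cells are 60.2, 63.3 and 68.1%, and border-associated macrophage-like cells are lowest in the Ncr1-cre poly(I:C) library at 5.09%.

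The microglia-like class held 7041, 6608 and 8781 cells with median UMIs of 4593, 5056 and 6006. Other measured properties of the class differed between libraries too. Cells with Xist UMIs and no Y gene UMI were 41.1, 48.1 and 32.1%, and cells with Y gene UMIs alone 28.4, 19.5 and 38.7%, so the mix of female and male fetuses differed. Hemoglobin RNA, which microglia do not make, took 0.753, 0.282 and 0.157% of UMIs, and the neutrophil genes S100a8 and S100a9 together 197, 60.1 and 30.4 CPM. The choroid plexus gene Ttr stood at 1917, 1531 and 385 CPM. Lists of erythroid markers and of hemoglobins each rested on the same 4 measured genes, all lower with each step (median log2 ratio -1.43 for poly(I:C) over saline and -0.83 for Gzmb-cko over Ncr1-cre poly(I:C)). The 4 measured neutrophil markers had medians of -0.70 and -0.69.

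The comparison of the Ncr1-cre libraries asks what poly(I:C) does. In microglia-like cells the monocyte-attracting chemokine gene Ccl2 stood at 147 CPM with poly(I:C) against 62.0 with saline, 2.37-fold higher (2.26 to 2.49). Zfp36, whose product destabilises cytokine mRNAs, was 2.07-fold higher (2.02 to 2.12) at 559.6 against 270.3 CPM, and Fos, an immediate early transcription factor gene, 2.02-fold higher (1.99 to 2.05) at 1149 against 569 CPM. Lower with poly(I:C) were the replication-dependent histone gene Hist1h2ap, at 79.1 against 257 CPM (3.25-fold, 3.12 to 3.39), although Hist1h1b, another such gene, was higher at 514 against 272 CPM, and Ifi27l2a, an interferon-inducible gene, at 51.7 against 109 CPM (2.11-fold, 1.99 to 2.23). Most genes differed little: 97.3% of 7859 genes lay within 1.5-fold.

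By list, 21 of 22 measured immediate early and heat shock genes were higher with poly(I:C) (median log2 ratio 0.49, percentile 100 of random lists), among them Ier2 at 212 against 114 CPM and Junb at 507 against 299 CPM. Of inflammatory cytokine, chemokine and NF-kB target genes, 15 of 19 were higher (median 0.43, percentile 100), such as Il1a, which encodes interleukin 1 alpha (65.5 against 36.3 CPM), the NF-kB inhibitor gene Tnfaip3 (28.2 against 15.8 CPM) and Ccl7 (19.3 against 9.66 CPM). Of homeostatic microglia genes, 18 of 20 were higher (median 0.28, percentile 99.99), with P2ry12, a purinergic receptor gene, at 1308 against 893 CPM, while Cx3cr1 was lower at 2279 against 2842 CPM. The 11 fixed microglia markers, which overlap that list, had a median of 0.34. Complement and phagocytosis genes were higher for 20 of 22 members (median 0.23, 0.14 under TMM), among them C5ar1 at 71.5 against 47.5 CPM. Unfolded protein and integrated stress response genes were higher for 16 of 17 (0.23, 0.14 under TMM), with Ppp1r15a at 106 against 66.7 CPM. Cholesterol genes were higher for 9 of 11 (0.26, 0.17 under TMM) and antigen presentation genes for 14 of 16 (0.18, 0.09 under TMM, percentile 92.9). Cell death and inflammasome genes were higher for 19 of 23 (0.17, 0.08 under TMM, percentile 90.8), with Nlrp3 at 49.6 against 36.1 CPM. Against the 20 genes nearest in length, median differences were 0.37 (0.18 to 0.67) for the immediate early and 0.37 (-0.05 to 0.855) for the inflammatory list. They were 0.15 (0.04 to 0.27) for homeostatic and 0.10 (0.05 to 0.27) for complement genes. Unfolded protein (0.10, -0.03 to 0.30) and cholesterol genes (0.12, -0.22 to 0.34) had intervals of both signs, like the inflammatory list.

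Type I interferon genes were divided: 16 of 24 were higher, with a median of 0.09 that turned to -0.03 when mitochondrial, ribosomal and hemoglobin genes were left out of the total and to -0.29 without cells with 2 or more cycle genes, and percentile 44.0. Ifit2 was higher at 14.3 against 10.1 CPM, while Rsad2 (9.45 against 15.8 CPM) and Ifitm3 (79.0 against 118 CPM) were lower. Lower as groups were nuclear genes of oxidative phosphorylation (30 of 33, median -0.30), with Ndufa2 at 249 against 392 CPM, ribosomal protein genes (67 of 77, median -0.30), and G2 and M phase genes (26 of 31, median -0.20), with Nusap1 at 68.5 against 99.3 CPM. Short genes were lower in general: genes other than ribosomal protein genes had a median of -0.54 under 500 bases and -0.29 from 500 to 700 bases. Against the 20 genes nearest in transcript length, the median difference was -0.09 (-0.29 to 0.03) for oxidative phosphorylation genes and -0.20 (-0.35 to -0.06) for ribosomal protein genes under 1000 bases, so most of the former goes with length. The 13 mitochondrially encoded genes went the other way from the nuclear ones (10 higher, median 0.31). Disease-associated and axon-tract microglia genes were lower for 15 of 24 (median -0.09, percentile 1.10): Gpnmb stood at 5.78 against 16.8 CPM and Spp1 at 385 against 636 CPM, and the 6 measured border-associated macrophage markers were all lower in the same cells (median -0.39). S phase genes had a median of -0.05, which turned to 0.01 without cells with 2 or more cycle genes, and iron, heme and oxidative stress genes one of -0.07. Small medians were also seen for interleukin 10 and alternative activation genes (0.10) and for growth factor and synapse-directed genes (0.12). The median of lipid efflux and lysosome genes was 0.09, turning to just below 0 under median of ratios scaling, and that of glycolysis and hypoxia genes was 0.04, turning to -0.05 under TMM scaling.

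Of the 12 genes named as higher, the remaining were Gng10, Mir142hg, Cep85l, Gal3st4, Nutf2, Phpt1, H2-T23, Zscan26 and Nme2 (1.91 to 2.53-fold). The 12 named as lower also included Stfa1, BC100530, Hist1h4d, Hist1h4h, Polr2l, Atp5k, Crip1, Rpl23a-ps3, Slirp and Mt2 (1.90 to 3.26-fold). Many of these have near-identical copies (the histones, stefins, H2-T23, Nme2, Nutf2, Gng10, Rpl23a-ps3 and Ifi27l2a) or overlap a gene on the same strand (Nme2, Gng10, Phpt1, Gal3st4), so their values are uncertain. The stefins Stfa1 and BC100530 are abundant in neutrophils and went with S100a8 and S100a9. Of the 10 genes named as higher with enough UMIs in the 4 other classes compared, 5 were higher in all of them (Gng10, Nutf2, Phpt1, Zscan26 and Nme2), and of the 12 named as lower, 8 were lower in all. Ccl2, Zfp36 and Fos were not among these: the log2 ratio of Ccl2 was 2.08 in border-associated macrophage-like cells and -0.52 in monocyte-like cells. Scaling set the balance of directions. By class totals 114 genes met the size rule as higher and 53 as lower (68.3% higher), by TMM 56 and 87 (39.2% higher), with the median of all genes at 0.10 and 0.01.

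**Figure D2:**
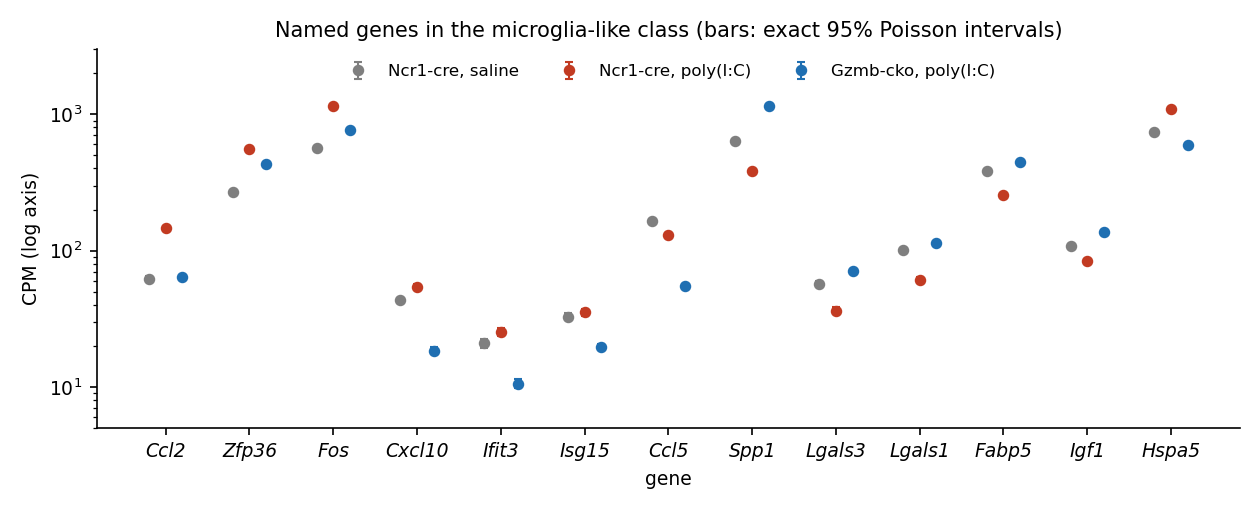
CPM of 13 genes (log axis) in the microglia-like class of the saline, Ncr1-cre poly(I:C) and Gzmb-cko poly(I:C) libraries, each point with an exact 95% Poisson bar that is mostly hidden by the point. Ccl2 stands at 62.0, 147 and 64.0 CPM and Spp1 at 636, 385 and 1152 CPM.

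The comparison of the poly(I:C) libraries asks what differs with the Gzmb deletion. In microglia-like cells Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes the secreted phosphoprotein osteopontin, stood at 1152 CPM in the Gzmb-cko library against 385 CPM in the Ncr1-cre library, 2.99-fold higher (2.93 to 3.04). Lgals3, encoding galectin-3, was 1.96-fold higher (1.85 to 2.09), Lgals1 1.85-fold (1.76 to 1.94), the fatty acid binding protein gene Fabp5 1.74-fold (1.70 to 1.79) and the growth factor gene Igf1 1.63-fold (1.56 to 1.70). The chemokine gene Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889) was 2.94-fold lower (2.73 to 3.17) at 18.45 against 54.3 CPM, Ccl5 2.38-fold lower (2.27 to 2.49) at 54.8 against 130.3 CPM, and Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) 2.30-fold lower (2.20 to 2.40) at 64.0 against 147 CPM. Hspa5, the endoplasmic reticulum chaperone gene also called BiP, was 1.83-fold lower (1.80 to 1.86) at 593 against 1085 CPM.

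Only 7 genes met the rule as higher, the others being Mid1 (1.69-fold) and Ifi27l2a (1.53-fold). Named as lower besides those above were the interferon-induced Ifit3 (2.39-fold, at 10.6 against 25.2 CPM) and Isg15 (1.80-fold), the heat shock gene Hsph1 (1.83-fold), the sodium and calcium exchanger gene Slc8a1 (1.86-fold), Cep85l (1.95-fold), and the histone genes Hist1h1b, Hist1h1e and Hist1h2ab, which are uncertain because of their copies. Cxcl10, Ccl5, Ifit3 and Isg15 came from few cells. Ifit3 was detected in 211, 164 and 187 cells and Isg15 in 401, 310 and 512 cells. In the Ncr1-cre and Gzmb-cko poly(I:C) libraries, 1% of cells held 84.0 and 84.4% of Ifit3 UMIs. For Isg15 these were 71.2 and 60.8%. Cxcl10 was detected in 144, 139 and 120 cells, and 1% of cells held 95.8 and 97.1% of its UMIs in the Ncr1-cre and Gzmb-cko poly(I:C) libraries. Without cells with 2 or more cycle genes, Cxcl10 was 1.13 times as high in the Gzmb-cko library as in the Ncr1-cre library. Ccl2 was spread over 1219, 1614 and 1596 cells. Spp1 was detected in 2059, 966 and 3058 cells, and 1% of cells held 57.3, 72.9 and 58.4% of its UMIs. For Lgals3 1% of cells held 51.85, 54.49 and 56.15%, so a small part of the class carried most Spp1 and Lgals3 RNA. These percentages were lower for Lgals1 (29.31, 25.08 and 29.08%), Fabp5 (23.71, 29.18 and 25.51%) and Igf1 (16.86, 22.33 and 19.38%).

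By list, 23 of 24 disease-associated and axon-tract microglia genes were higher in the Gzmb-cko library (median log2 ratio 0.28, percentile 100), with Gpnmb at 17.0 against 5.78 CPM and Cd9 at 1112 against 869.5 CPM. The 6 border-associated macrophage markers were all higher in the same cells (median 0.48). Gpnmb was detected in only 203, 76 and 281 cells of the class. Lower were 16 of 19 inflammatory and NF-kB genes (median -0.41, percentile 0), with Il1a at 42.1 against 65.5 CPM, and 20 of 22 immediate early and heat shock genes (median -0.31, percentile 0). Also lower were 15 of 17 unfolded protein and integrated stress response genes (median -0.29), with Pdia4 at 117 against 149 CPM, and 15 of 24 interferon genes (median -0.20, percentile 0.50, turning to 0.03 when members needed a mean of 50 CPM), with Ifitm3 at 56.6 against 79.0 CPM. Homeostatic genes were lower for 18 of 20 (median -0.18, -0.07 under TMM), with P2ry12 at 989.5 against 1308 CPM, the microglia markers had a median of -0.19, and complement and phagocytosis genes were lower for 17 of 22 (median -0.16). Higher were 31 of 33 nuclear oxidative phosphorylation genes (median 0.21), 76 of 77 ribosomal protein genes (0.18), 21 of 27 S phase genes (0.11, turning to -0.23 without cells with 2 or more cycle genes) and 18 of 31 G2 and M phase genes (0.08), against 10 of 13 mitochondrially encoded genes lower (-0.13). Iron, heme and oxidative stress genes had a median of 0.06 and cholesterol genes one of 0.01.

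For the other lists the direction followed the scaling. Medians were -0.11 by totals and just above 0 under median of ratios scaling for antigen presentation, and -0.10 by totals and 0.01 under TMM for both cell death and interleukin 10 genes. They were -0.07 and 0.04 for growth factors, -0.04 and 0.07 for lipid efflux and lysosome genes, and -0.04 and 0.07 for glycolysis. TMM moved the median of all genes from -0.08 to 0.03, and the genes meeting the size rule from 7 higher and 54 lower (11.5% higher) to 13 and 22 (37.1% higher). Ratios in this comparison also fell with transcript length, with a Spearman rho of -0.51 across 7764 genes, which are not independent replicates. Genes of 4000 bases or more had a median log2 ratio of -0.18, and genes of 500 to 700 bases one of 0.19. Among random lists matched on length too, the percentiles were 100 for the disease-associated list, 0 for the inflammatory list, 0.04 for the interferon list and 2.06 for the homeostatic list. Against the 20 genes nearest in length, median differences were 0.31 (0.19 to 0.61) for the disease-associated list, -0.26 (-0.38 to -0.07) for the immediate early list and -0.37 (-0.68 to 0.01) for the inflammatory list. They were smaller for the interferon list (-0.08, -0.59 to 0.17), the homeostatic list (-0.06, -0.16 to 0.04) and oxidative phosphorylation (0.07, 0.01 to 0.10). For ribosomal protein genes they were 0.07 (0.05 to 0.10) over all 77 and 0.04 under 1000 bases. A part of the homeostatic, oxidative phosphorylation and ribosomal medians thus went with length. For the interferon and homeostatic lists the length checks differed, as their percentiles among length-matched lists were low.

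Several named genes were not limited to microglia-like cells. Hspa5 had log2 ratios of -0.91, -0.74, -1.24 and -0.34 in border-associated macrophage-like, monocyte-like, choroid plexus-like and neuron-like cells. Spp1 had 0.18, 0.03, 1.59 and 4.88 in the same classes, and Lgals3 -0.22, -0.16, 0.63 and 2.12. Lgals1 had 0.28, 0.07, 0.85 and 1.05. Neuron-like cells carried C1q RNA, a microglial product, at 7108, 2971 and 6768 CPM, so their ratios also reflect myeloid content. With the border-associated cluster led by Spp1 counted as microglia-like, Spp1 was 2.23-fold and Lgals3 1.60-fold higher in the Gzmb-cko library, and Spp1 was 0.638 times as high with poly(I:C) as with saline in the Ncr1-cre libraries.

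Gzmb-cko with poly(I:C) against saline differs in genotype and in treatment, and shows where that library lies relative to the saline one. Spp1 was 1.81-fold higher (1.78 to 1.84) than with saline, while Ccl5 was lower at 54.8 against 164 CPM and Cxcl10 2.33-fold lower (2.16 to 2.52). Ccl2, at 64.0 against 62.0 CPM, lay near its saline level. The other named genes were Nutf2, Mir142hg, Gng10, Rpa3 and Phpt1 as higher (1.86 to 2.23-fold) and Stfa1, BC100530, Hist1h4d and Hist1h4h as lower (2.38 to 8.64-fold), most of them uncertain for the reasons given above.

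By list, 21 of 24 disease-associated and axon-tract genes were higher than with saline (median 0.20, percentile 100), as were 17 of 22 immediate early and heat shock genes (0.21, percentile 100), 16 of 22 complement genes (0.14), 10 of 11 cholesterol genes (0.22), 10 of 14 growth factor genes (0.13) and 9 of 13 mitochondrially encoded genes (0.23). Lower were 16 of 24 interferon genes (-0.11, percentile 0.22), with Rsad2 at 5.25 against 15.8 CPM, 23 of 33 oxidative phosphorylation genes (-0.14), 50 of 77 ribosomal protein genes (-0.08) and 20 of 31 G2 and M phase genes (-0.11). Inflammatory and NF-kB genes had a median of 0.04 (percentile 65.9), which turned to -0.01 with mitochondrial, ribosomal and hemoglobin genes left out of the total. Medians were 0.09 for homeostatic genes, 0.14 for microglia markers, 0.08 for antigen presentation, 0.08 for cell death, 0.07 for S phase, 0.04 for border-associated macrophage markers, -0.04 for iron and heme genes, -0.04 for interleukin 10 genes, -1.32 for neutrophil markers and -2.20 for hemoglobins. Those of unfolded protein response, glycolysis and lysosome genes were at or within 0.01 of 0 and changed sign under TMM. Length mattered here too, with a Spearman rho of -0.39 across 7764 genes and 0.50 among 469 genes under 1000 bases. Against the 20 genes nearest in length the median difference was 0.10 (0.06 to 0.26) for the disease-associated list, 0.17 (0.07 to 0.35) for the immediate early list, -0.08 (-0.62 to 0.02) for the interferon list and -0.06 (-0.12 to 0.05) for oxidative phosphorylation. By totals 23 genes met the size rule as higher and 43 as lower, and 27 and 39 by TMM.

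**Figure D3:**
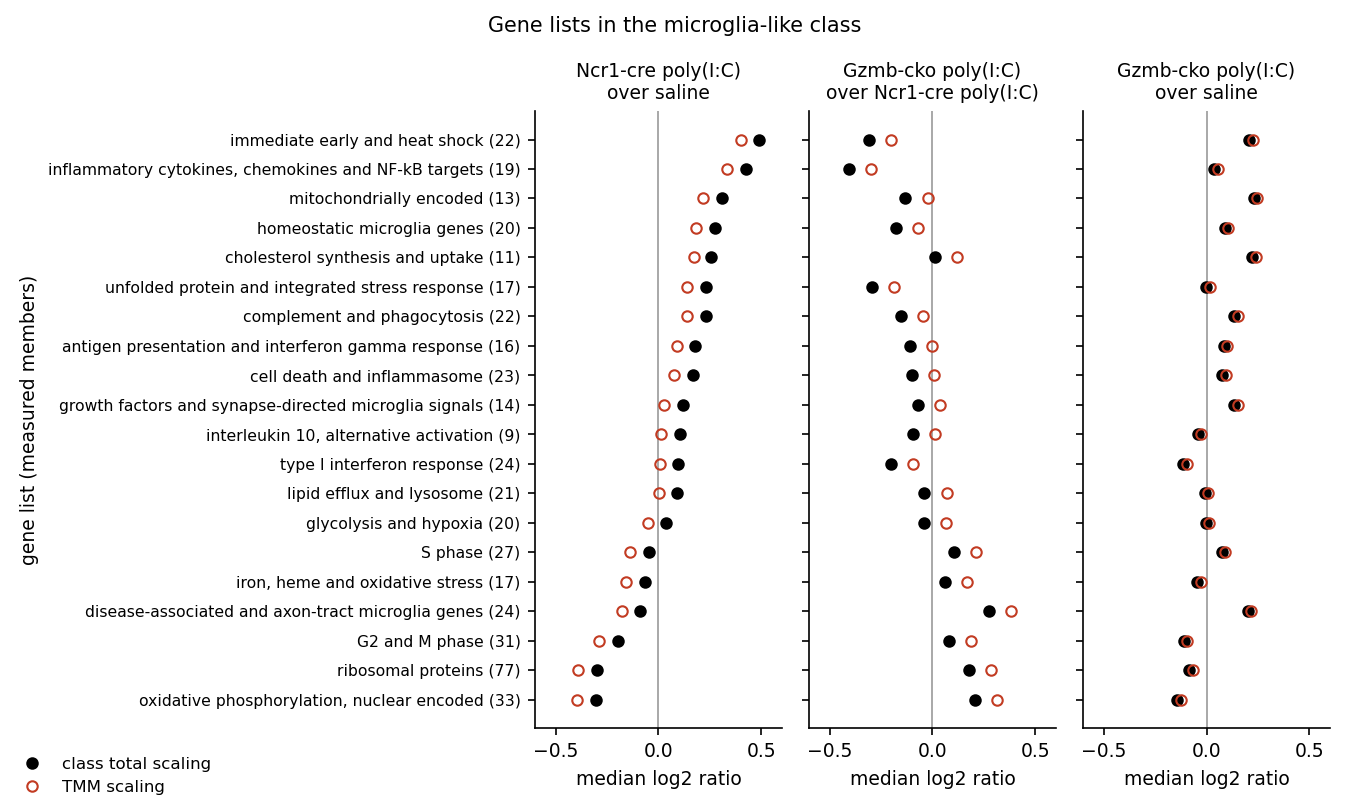
Median log2 ratio (horizontal axis) of 20 gene lists in the microglia-like class for each pair of libraries, with filled black points for scaling by class totals and open red points for TMM. The inflammatory and NF-kB list lies at 0.43, -0.41 and 0.04 by class totals for poly(I:C) over saline, Gzmb-cko over Ncr1-cre poly(I:C), and Gzmb-cko over saline, turning to -0.01 in the last when mitochondrial, ribosomal and hemoglobin genes are left out of the total.

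Genes past the size rule in the first comparison mostly went the other way in the second. Of the 114 higher with poly(I:C), 109 were lower in the Gzmb-cko library than in the Ncr1-cre poly(I:C) library, and of the 53 lower, 42 were higher, together 90.4% of 167 genes (84.9 to 94.4). This interval treats the genes as independent, which they are not. The Ncr1-cre poly(I:C) library is shared by both comparisons, which by itself gives opposed ratios, and 66.3% of all genes were lower in the second comparison. With its cells split at random so that each comparison used separate cells, 90.3 and 86.1% of the genes were opposed. A split of cells removes shared counting error but not what that 1 library has in common, such as its preparation. The covariance of the log2 ratios across genes was -0.0279, against -0.00118 in simulated unchanged libraries. The correlation was -0.597 against -0.566, so the size of the correlation alone does not tell the 2 cases apart. The simulated libraries held counting error only. The larger covariance therefore does not separate an effect of the groups from what the shared library has in common.

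Cells with at least 3 genes of the G2 and M phase list were 36.1% (35.0 to 37.3), 25.3% (24.2 to 26.6) and 30.8% (29.8 to 31.8) of microglia-like cells thinned to 3142 UMIs. Thinning left out 32, 1400 and 805 cells with fewer UMIs. Mki67, a proliferation marker gene, was detected in 2348 of 7041, 1360 of 6608 and 2336 of 8781 cells without thinning, which follows the order of these shares. Its level in the class, at 348, 327 and 255 CPM, does not follow that order. Among subclusters of the microglia-like class, the one led by Ccl5, Cxcl10, Ifit3 and Isg15 held 3.99% (3.55 to 4.48), 2.94% (2.54 to 3.37) and 1.401% (1.165 to 1.669) of cells, in shares drawn from genes that themselves differed between libraries. The largest subclusters separated by library and are not compared.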

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

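The tests of transcript length as the whole or a part of the cause, of the Gzmb-cko part of the ribosomal pattern in other cell classes, and of free RNA for single genes were chosen only after the result was seen; the other tests were stated beforehand. Of the barcodes of the Ncr1-cre poly(I:C) library, 27.7% (27.0 to 28.5) failed the limits on genes and mitochondrial UMIs, against 12.1% with saline and 12.1% in the Gzmb-cko library, a share of data outside the comparisons above the saline level. A small unnamed cluster with markers of both fibroblasts and endothelial cells made up 0.201% of the kept cells of that library (21 cells, 0.125 to 0.307), against 0.06% (7 cells) with saline and 0.023% (3 cells) in the Gzmb-cko library.

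Ribosomal protein genes were lower in microglia-like cells of both poly(I:C) libraries than with saline. For the Ncr1-cre library the same held in the other classes: the median log2 ratio was -0.28 in choroid plexus-like and -0.30 in neuron-like cells, the higher of these being -0.2819, which is consistent with a difference between whole libraries. For the Gzmb-cko library the classes were divided, with -0.14 in border-associated macrophage-like and -0.13 in monocyte-like cells against 0.03 in neuron-like and 0.316 in choroid plexus-like cells. As the make-up of the choroid plexus-like class also differed, a shared difference cannot be told apart there. By the planned test, an effect of transcript length over all genes cannot be told apart, because the Spearman rho across all other genes was 0.1373 for the Ncr1-cre library, between the bounds set for and against it. Among 469 other genes under 1000 bases, the range of most ribosomal protein genes, rho was 0.4878 for the Ncr1-cre and 0.4961 for the Gzmb-cko library, which is consistent with length as a part of the cause. Against length as the whole cause, ribosomal protein genes under 1000 bases were lower than the 20 other genes nearest in length, with a median difference of -0.2019 (-0.35 to -0.06) in the Ncr1-cre and -0.1809 (-0.31 to -0.01) in the Gzmb-cko library. Both intervals treat the genes as independent, which they are not. An effect of poly(I:C) on all cell classes remains open and was not tested.

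Spp1, Lgals3, Fabp5, Lgals1 and Igf1 were higher in the Gzmb-cko than in the Ncr1-cre poly(I:C) library. Free RNA would raise Spp1 in every class, and the bound set beforehand against it was a rise of at most 25% of that in microglia-like cells in both choroid plexus-like and neuron-like cells. It was met in choroid plexus-like cells (4.86%) and missed in neuron-like cells (103%), so for the 5 genes free RNA cannot be told apart by the planned test. Neuron-like cells of that library also carried C1q RNA of microglia at 6768 CPM, against 912 CPM in choroid plexus-like cells, so their rise also reflects microglial RNA or cells in the class. The upper bound of the whole level in choroid plexus-like cells of the Gzmb-cko library was set against the rise in microglia-like cells. It was 389% of that rise for Lgals1 and 295% for Lgals3. For Spp1, Fabp5 and Igf1 it was 8.26, 38.1 and 53.7%, which argues against free RNA as the whole cause of their rise. Lgals1 and Lgals3 rose in choroid plexus-like cells too, Lgals1 to 186 from 103 CPM (to 113 from 61.1 CPM in microglia-like cells) and Lgals3 to 92.2 from 59.3 CPM (to 71.1 from 36.2 CPM in microglia-like cells), so for them it stays open. Without cells that had a UMI of 7 border-associated macrophage markers the median ratio of the 5 genes was 1.525, and with a floor of 3133 UMIs in every library 1.956, against 1.85 in the full class, so neither mixed cells nor cells of few UMIs account for the whole rise. A different microglial state with the Gzmb deletion remains open and was not tested. The mix of fetal sexes, the litters and the trend with transcript length were not separated from genotype.

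Immediate early and NF-kB target genes were higher with poly(I:C) than with saline in microglia-like cells. A handling response of all cells would raise the immediate early list everywhere. Its median was -0.29 in choroid plexus-like and -0.26 in neuron-like cells, the higher being -0.2588, below the bound set beforehand against such a response. Both classes also held less microglial C1q RNA with poly(I:C), at 619 against 1662 CPM and 2971 against 7108 CPM. With less myeloid RNA in these classes, their medians cannot decide on a handling response. With the floor of 3133 UMIs the NF-kB list kept a median of 0.4655, which argues against cells of few UMIs. The immediate early list was higher in border-associated macrophage-like (0.67) and monocyte-like cells (0.29). A response to isolation, of myeloid cells or of all cells, may thus remain, as may an effect of the treatment. These explanations were not separated.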

How the results depend on the processing

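The settings with a floor of 3133 UMIs, the lists matched on length, thinning to 3133 UMIs and the class with the cluster led by Spp1 were chosen after the data were seen. Of the ratios of single genes under other settings, 3443 stayed within their counting interval, 974 left it and 3 were counted as reversed. A reversal was counted only where the main ratio was at least 1.5-fold in either direction. Smaller ratios may thus have changed direction without being counted. Of the medians of the 5 lists that answer the first 2 comparisons, 163 stayed within the bounds of the main value, 6 left them and 1 was counted as reversed. These bounds are intervals over the members of a list and can be wide. For the interferon list of poly(I:C) over saline they ran from -0.04 to 0.21, so a median could change sign within them. Inflammatory and NF-kB medians ranged from 0.30 to 0.53 for poly(I:C) over saline and from -0.46 to -0.20 for Gzmb-cko over Ncr1-cre poly(I:C). Disease-associated medians ranged from -0.18 to -0.03 in the former comparison and from 0.15 to 0.39 in the latter. The doublet caller found 0 doublets in the saline library under the looser filter and 1 in the Gzmb-cko library under the stricter one, so it did not work there. In the main setting it called 3.77, 2.965 and 4.15% of cells, below the expected 11.06, 11.91 and 12.24%, so doublets may remain. No replicate could be left out.

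Reversed without cells with 2 or more cycle genes, a setting that keeps 1297, 1569 and 1405 cells, were the ratios of Cxcl10 (1.1348) and Mmp12 (9.9275) for Gzmb-cko over Ncr1-cre poly(I:C) and of Arg1 (0.6863) for poly(I:C) over saline, and the S phase medians of the same comparisons (-0.232 and 0.0075). The setting without cells with 2 or more cycle genes left out most of the class, which held 7041, 6608 and 8781 cells. It counts genes without thinning and so depends on UMIs per cell, and is not a removal of cycling cells alone. With a minimum of 50 CPM the interferon median of Gzmb-cko over Ncr1-cre poly(I:C) reversed to 0.0339. The cause was not tested. The homeostatic median of that comparison was -0.0711 under TMM, -0.0674 under median of ratios and -0.1053 with per-cell means. It was -0.0956 without cells with 2 or more cycle genes. The interferon median of poly(I:C) over saline was -0.2913 without cells with 2 or more cycle genes. The immediate early median of Gzmb-cko over Ncr1-cre poly(I:C) was -0.4218 with the stricter filter and ranged from -0.4218 to -0.1646 over the settings. The cause was not tested.

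Microglia-like shares (saline, Ncr1-cre poly(I:C), Gzmb-cko) were 55.817, 59.919 and 66.973% with the looser filter, 57.977, 58.444 and 63.308% with doublets kept, 57.34, 60.67 and 65.35% at resolution 2.0, 58.358, 59.531 and 62.464% when centred per library, and 65.352, 65.342 and 69.18% with erythroid-like cells left out. The stricter filter gave 61.523 and 69.124% in the poly(I:C) libraries, and the floor 64.694 and 71.633%. The Gzmb-cko share was highest in each, and the order of the other libraries turned only with erythroid-like cells left out, whose shares differ. Cycling shares were 44.086, 32.642 and 39.23% with 2 genes, and 41.443, 30.978 and 40.2% without thinning. The share of the interferon subcluster in the Gzmb-cko library was 1.799% when centred. The cause was not tested.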

Other observations

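Genes of other classes named here followed the rule set before the data were examined, except Ccl5 in the Ncr1-cre libraries, which was picked after its values were seen; no test was chosen after the result was seen. In border-associated macrophage-like cells of the Ncr1-cre libraries the chemokine genes Ccl7 and Ccl2 were higher with poly(I:C), while the chemokine gene Ccl5 was lower at 23.9 against 47.9 CPM. Ccl7 was at 109.5 against 22.9 CPM with saline (4.79-fold, 3.97 to 5.79) and Ccl2 at 227 against 53.0 CPM (4.28-fold, 3.78 to 4.85). In the Gzmb-cko library they stood at 75.6 and 139 CPM. Cyr61, a matrix-associated signalling gene, and Bmp2, a growth factor gene, were higher too, at 78.2 against 19.5 and 45.8 against 12.9 CPM. All 22 immediate early and heat shock genes were higher with poly(I:C) in this class (median log2 ratio 0.67, 0.45 under TMM), and 9 of 10 interleukin 10 and alternative activation genes (0.58). Cd163, a scavenger receptor gene of border macrophages, was at 59.9, 180.4 and 168 CPM. G2 and M phase genes were higher in all 29 members in the Gzmb-cko library against saline (median 0.70). Between the poly(I:C) libraries, Hmox1, encoding heme oxygenase 1, was 1.65-fold higher with the Gzmb deletion and Rsad2 2.31-fold (1.69 to 3.22), while Ccl5 was 2.13-fold lower. The share of this class in its cluster led by Spp1 differed between libraries (71.0, 48.4 and 44.1%), and scaling moved its all-gene median for poly(I:C) over saline from 0.20 to -0.02 under TMM.

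In monocyte-like cells the interferon genes were highest in the Gzmb-cko library: all 35 measured were higher than with saline (median 0.56), and antigen presentation genes had a median of 0.53. Saa3, an acute phase gene, stood at 79.5, 104 and 576 CPM, 7.25-fold above saline (6.52 to 8.07), and Slfn4 at 22.99, 45.7 and 67.7 CPM. Proliferation genes peaked in the Ncr1-cre poly(I:C) library, where Mki67 was at 104 CPM against 71.3 with saline and 33.98 in the Gzmb-cko library, and 25 of 26 G2 and M phase genes were higher than with saline (median 0.54) and 25 of 26 lower with the Gzmb deletion (median -0.69). Marco, a scavenger receptor gene, was 7.01-fold higher in the Gzmb-cko than in the Ncr1-cre poly(I:C) library. Fabp4, a fatty acid binding protein gene, was 3.28-fold higher with poly(I:C) than with saline. Fabp4 was also a leading gene of a small cluster that held 40, 16 and 4 cells of the class (4.35, 2.38 and 0.73%). The neutrophil granule list, with too few members above the minimum in microglia-like cells, had medians of 0.32, -0.39 and 0.28 over 7 genes here. Microglia markers in this class had medians of -1.63 and 0.86 in the first 2 comparisons, so its content of microglial RNA or cells differed between libraries.

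Choroid plexus-like and neuron-like cells differed in make-up between libraries. The cilia genes Ccdc153 and Tmem212 were at 107 and 71.8 CPM in choroid plexus-like cells of the Ncr1-cre poly(I:C) library, against 0.271 and 0 CPM with saline and 0.907 and 0 CPM in the Gzmb-cko library. In neuron-like cells Hcrt, which encodes the hypothalamic peptide orexin, was at 0.831, 0 and 75.6 CPM, and Six3, a forebrain patterning gene, at 88.1, 333 and 38.5 CPM.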
